A study of Mus musculus with 4 samples.

How the data were processed

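The study measured where the zinc finger protein Prdm5 sits on chromatin by chromatin immunoprecipitation followed by sequencing (ChIP-seq). Mouse embryo fibroblasts (MEF) of the C57BL/6 strain were used, 2 libraries from wild-type cells and 2 from Prdm5 lacz/lacz cells. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sonicated, and DNA was recovered with custom polyclonal PRDM5 antibodies. The titles distinguish the libraries of each genotype as ab1 and ab2. These numbers were kept as replicate names, but what they stand for is not given in the sources used here. They may name different antibodies, in which case the libraries of a genotype would not be replicates of the same measurement. The design text gives the lacz/lacz libraries as the measure of background. The submitters' processing notes name Bowtie and the mm9 build. The peak caller, its threshold, the Bowtie version, and whether libraries were pooled before peak calling are not given in the sources used here.

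The values used here come from 1 deposited peak list for the whole series, in bp. Per the file headers, each row gives a peak's chromosome, start, end and width in bp, the gene to which it was assigned with that gene's Ensembl identifier, bounds, strand, Entrez identifier and description, and the signed distance in bp to the gene start. Width equalled end minus start plus 1 in all 1490 rows. The deposited distance equalled, in all 1490 rows, the distance from the lower-coordinate end of the peak to the gene start, with negative values upstream. The list carries no fold enrichment, score, p-value, read number or value per library, so the depth behind each peak is unknown. Neither the spread between libraries of a genotype nor the difference between genotypes at a given peak could be computed. Peak width is a property of the called region and was not taken as a measure of occupancy.

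From these values the distance from each peak's midpoint to the start of its assigned gene was computed and used throughout. Coordinates are those of the list and mm9 is the build in the submitters' processing notes. Gene symbols were taken by Entrez identifier from an NCBI RefSeq gene table of assembly GRCm38.p6, which was used only for names, biotypes and the chromosome of each gene; 1097 of 1103 distinct Entrez identifiers matched, and 283 peaks without a symbol keep the description in the list. No genome sequence or mm9 annotation was used here, so exons, introns and sequence motifs were not analysed, and gene bounds are known only for genes to which the list assigns a peak. A peak was said to lie in a gene body when it overlapped those bounds by at least 1 bp.

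Gene lists (23), tests, windows and the rule for naming genes were fixed before the data were examined. A target gene was one assigned a peak whose midpoint lay within 10 kb of its start. Each list was compared with the other protein-coding genes of the RefSeq table (21896 in all; a few list members are of other biotypes) by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 23 lists and a threshold of 0.05. Odds ratios were computed with 0.5 added to each cell. Peaks per chromosome were compared with chromosome length, taken as the last position that the list gives on each chromosome, by a chi-square statistic with 100000 Monte Carlo draws. Adjacent peaks with midpoints within 10 kb were counted against 1000 uniform placements of the same number of peaks per chromosome, one-sided. These placements ignore unmappable sequence and the positions of genes. Widths were compared by a two-sided permutation test of the difference in medians with 100000 resamples. A test of peak strength by location had been planned, but the list gives no strength; the comparison of widths was made in its place and describes the extent of the called regions only. Shares carry 95% Wilson intervals, which cover counting error only. The random seed was 7.

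The planned rule named genes by the authors' fold enrichment or score. As the list holds neither, width took its place: the genes of the 15 widest peaks were named, up to 4 members of each list with the widest peaks, and Prdm5, Ctcf, Col1a1, Col1a2, Col3a1, H19 and Igf2 in any case. Other genes given as the members of a count, and Fcnb and Olfm2, were named after their values were seen. The account of peaks within collagen gene bodies, including the grouping of collagens by type, was also added after the data were seen; there the distance of a peak was taken to the nearest start among the genes whose bodies hold it. The tests planned on motifs, on promoter share against random placements and on values per library could not be made from the list. Alternatives were the window around the gene start, the peak edge in place of the midpoint, the peaks wider than the median, other backgrounds for the gene lists, gene number in place of chromosome length, leaving out the X chromosome, merging close peaks, and leaving out peaks in collagen bodies or over 5 kb wide.

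The tests were tested on simulated data. In 100 simulated target sets drawn over 21922 genes, with a planted target share of 30.0% in the Wnt pathway and Hox lists, both planted lists were called in 100.0% of sets and unchanged lists in 0.238% of tests. Smaller lists and lower shares were not simulated. Of sets with no planted effect, the clustering test called 7%, the chromosome test 7% and the width test 6%. For clustering and chromosomes these sets were drawn from the model that the test assumes, so the rates do not check that model. Simulated widths followed a normal distribution. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.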

Results

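Chromatin bound by Prdm5, a zinc finger protein with a PR domain, was profiled by ChIP-seq in mouse embryo fibroblasts, connective tissue cells grown from embryos. The series comprised 4 libraries, 2 from wild-type cells and 2 from Prdm5 lacz/lacz cells, which served to measure background. The title of the series speaks of embryonic stem cells, whereas every library here was labelled as fibroblast. The data analysed here were 1 peak list for the series, without values per library, and how the lacz/lacz libraries entered it is not given in the sources used here. The list records where peaks were called, and the depth behind each peak is unknown. No comparison of libraries within a genotype and no test between genotypes could be made. Intervals given for shares cover counting error only. It held 1490 peaks on 20 chromosomes, assigned to 1361 genes. Their median width was 624.5 bp, and 1425 were narrower than 1 kb.

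The first question was where the peaks lay relative to genes. Peaks concentrated at gene starts. The midpoint of 519 peaks lay within 1 kb of the start of the assigned gene, which is 34.8% of the list (95% Wilson interval 32.5% to 37.3%). By the position classes of the list, 307 peaks (20.6%) spanned a gene start, 459 (30.8%) lay inside a gene, 455 (30.5%) upstream and 249 (16.7%) downstream of one. The number of peaks per kb of distance was 519 within 1 kb of the start, 55.8 between 1 and 5 kb and 10.3 between 10 and 50 kb. A decline with distance is partly built into an assignment by proximity. A further 198 peaks (13.3%) lay more than 50 kb from the start of their assigned gene. Within 1 kb, 299 midpoints lay downstream of the start and 220 upstream, a downstream share of 57.6% (95% Wilson interval 53.3% to 61.8%, two-sided exact binomial p = 0.0006). The start used is the outer bound of the gene, so a peak at any start further inside counts as downstream. This share is thus no measure of a preference for either side.

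**Figure D1:**
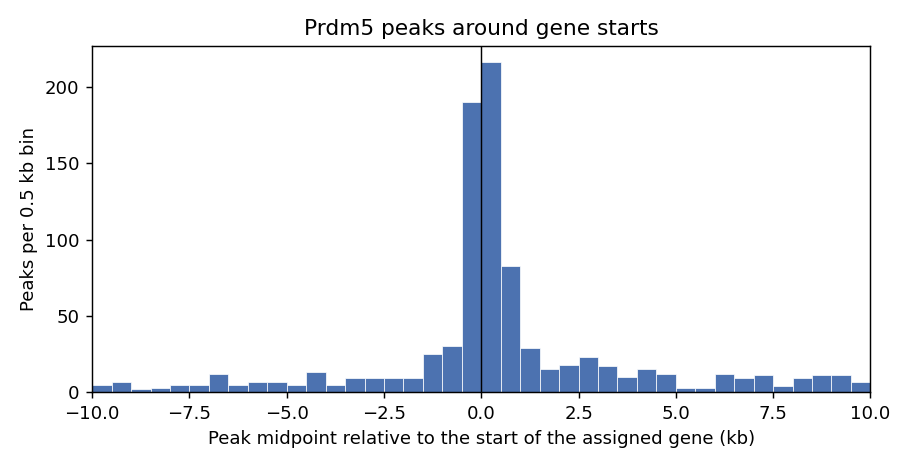
Number of peaks per 0.5 kb bin (y axis) against the position of the peak midpoint relative to the start of the assigned gene in kb (x axis, negative upstream; vertical line at the start). Only peaks within 10 kb are drawn, 880 of 1490, and the bins next to the start are the tallest.

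Genes with a peak at the start included Serpinh1, the collagen chaperone of the endoplasmic reticulum. Its peak, at chromosome 7, 106500538 to 106502435, was 1898 bp wide and spanned the gene start. Bmp4, a bone morphogenetic protein, had a peak with its midpoint 0.3 kb inside the gene, and Pdgfra, a platelet-derived growth factor receptor of mesenchymal cells, had 2 peaks, with midpoints 0.832 and 4.4 kb from the start. Among other zinc finger genes, peaks spanned the starts of Zfp606, Zfp454 and Zfp672, and that of Zfp219 lay 1.13 kb inside the gene. Peaks within 1 kb of the start were slightly wider than the others, with medians of 649 bp (n = 519) and 618 bp (n = 971). The medians differed by 31 bp (two-sided permutation p = 0.00012), although the distributions overlapped broadly, with interquartile ranges of 544 to 757.5 bp and 517 to 709 bp.

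The gene lists fixed in advance asked which groups of genes were bound. Collagens and Hox genes were targets more often than other protein-coding genes, and olfactory receptors less often. Of 44 collagen genes 9 had a peak midpoint within 10 kb of the start (20.5%, 95% Wilson interval 11.2% to 34.5%), against 3.33% of the other genes (odds ratio 7.77, Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00015). Of 39 Hox genes, the homeodomain factors that pattern the body axis, 8 were targets (20.5%, 95% Wilson interval 10.8% to 35.5%; odds ratio 7.83, exact test adjusted p = 0.00029). A peak spanned the start of Hoxa7 at chromosome 6, 52167800 to 52168713. Another lay 2.98 kb upstream of Hoxc12 and was 1102 bp wide. Peaks of Hoxd8 and Hoxc4 had midpoints 2.1 kb and 6.62 kb downstream of the gene starts. Only 1 of 1117 olfactory receptor genes was a target, against 3.54% of the other genes (odds ratio 0.0366, exact test adjusted p = 1.9e-14). That gene was Olfr834, with a midpoint 7.24 kb downstream of its start. The exact tests take genes as independent, although members of a family can be neighbours, as Hoxc12 and Hoxc13 are on chromosome 15. Their p-values may therefore be too small. How well reads map to receptor genes was not examined. The collagen call was lost within 1 kb of the start (0 of 44, exact test adjusted p = 1) and within 5 kb (5 of 44, exact test adjusted p = 0.0552), and its adjusted p ranged from 2.9e-15 to 1 over the alternatives. The Hox call was lost within 1 kb (2 of 39, exact test adjusted p = 0.82) and among peaks wider than the median (2 of 39, exact test adjusted p = 0.619), over a range of 0.00046 to 0.82.

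**Figure D2:**
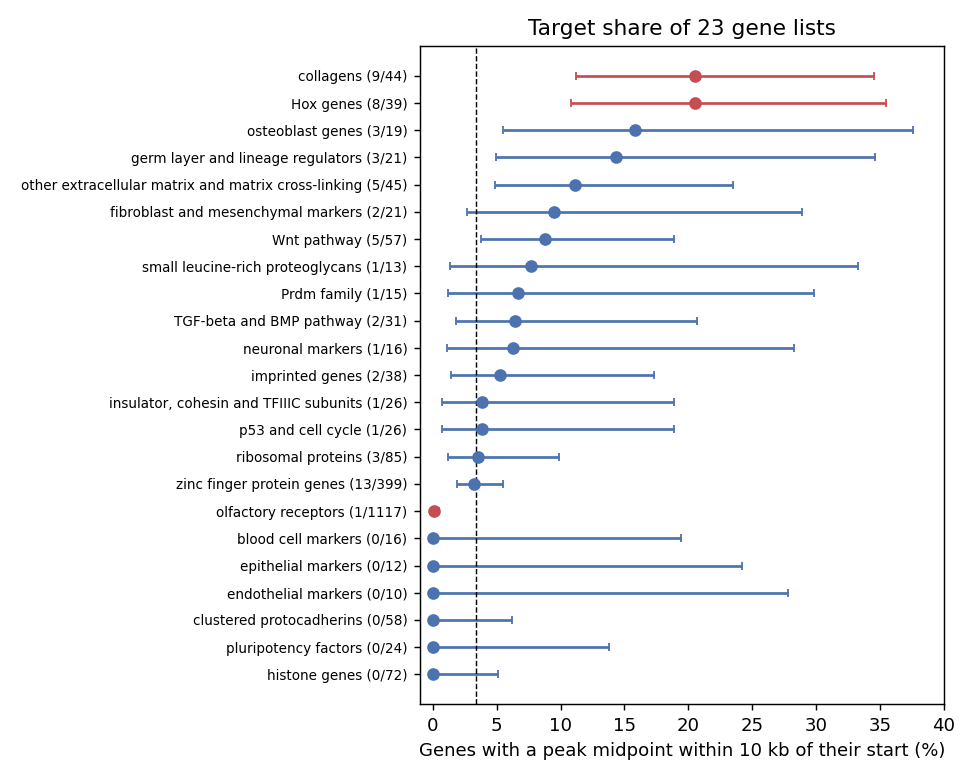
Share of the genes in each of 23 lists that had a peak midpoint within 10 kb of the start (x axis, percent; points, with bars for 95% Wilson intervals; targets and list size in parentheses). Red lists passed an adjusted p of 0.05, blue lists did not, and the dashed line marks the 3.36% of all protein-coding genes that were targets; collagens and Hox genes lie at 20.5%.

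The other 20 lists did not pass the threshold. Among the groups nearest to bone and matrix biology, 3 of 19 osteoblast genes were targets (Bmp4, Dlx3 and Satb2; exact test adjusted p = 0.113). Of 45 other matrix and matrix cross-linking genes 5 were targets (exact test adjusted p = 0.098), among them Serpinh1, Acan, the main proteoglycan of cartilage, with a peak 0.614 kb upstream, and Timp1, a metalloproteinase inhibitor, with a peak over the gene end. Eln, which encodes elastin, was assigned a peak 21.5 kb upstream and so was not counted. The small leucine-rich proteoglycans had 1 target of 13, Fmod (fibromodulin, which binds collagen fibrils), with 2 peaks inside the gene 4.64 and 6.14 kb from its start (exact test adjusted p = 0.646). In the Wnt pathway 5 of 57 genes were targets (exact test adjusted p = 0.139). Peaks lay inside Wnt10b and Rspo1 at 0.548 and 0.766 kb from the start, inside and upstream of Wnt3a at 0.537 and 3.1 kb, and 7.57 kb upstream of Wnt10a. Of 21 germ layer and lineage regulators 3 were targets (Mixl1, Hand1 and Isl1; exact test adjusted p = 0.123), while Cdx2, a regulator of trophectoderm and gut, was assigned a peak 14.1 kb downstream of its start. Both this list and the matrix list passed when the window was 50 kb (5 of 21, exact test adjusted p = 0.012, and 7 of 45, exact test adjusted p = 0.0178). Fibroblast and mesenchymal markers had 2 targets of 21, Pdgfra and Prrx1 (exact test adjusted p = 0.448). The TGF-beta and BMP pathway had 2 of 31, Bmp4 and Bmp7 (exact test adjusted p = 0.585).

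The title of the series names insulator binding proteins. Genes encoding insulator, cohesin and TFIIIC subunits did not pass the threshold, with 1 target of 26 (exact test adjusted p = 0.797). That target was Wapl, the cohesin release factor, with a peak 0.283 kb upstream. The peaks assigned to Pds5a and Chd8 lay 20.6 and 20 kb upstream, and no peak was assigned to Ctcf. This list asks whether those genes were bound and says nothing about sites shared with their products. Imprinted genes had 2 targets of 38 (exact test adjusted p = 0.646), Gnas and Zim1, the latter with a peak over its start. Cdkn1c, an imprinted cell cycle inhibitor, was assigned peaks 28.1 and 86.2 kb downstream of its start, the second of them 1459 bp wide, and a peak lay inside Plagl1, 36.8 kb from the start. No peak was assigned to H19 or Igf2. Cell cycle and p53 genes had 1 target of 26, Ccne1 (cyclin E1; exact test adjusted p = 0.797), besides a peak inside Cdkn2a 12.2 kb from the start and 1 that lay 101.3 kb upstream of Ccnd1. Ribosomal protein genes had 3 of 85 (exact test adjusted p = 0.976), with a peak over the start of Rpl39, and zinc finger protein genes 13 of 399 (exact test adjusted p = 1). None of 72 histone genes, 58 clustered protocadherins or 24 pluripotency factors was a target (exact test adjusted p = 0.459, 0.585 and 1). Among markers of other cell types, Gad1 was the target among 16 neuronal genes (exact test adjusted p = 0.646), and none of 16 blood, 10 endothelial and 12 epithelial markers was a target (exact test adjusted p = 1 for each).

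Within the Prdm family 1 of 15 genes was a target (exact test adjusted p = 0.646), Prdm15, with a peak over its start. Prdm5 itself held 1 peak, at chromosome 6, 65747096 to 65747639, inside the gene and 18.4 kb from its start. Where the lacz cassette of the mutant allele lies relative to this peak is not given in the sources used here. Prdm1 was assigned 3 peaks, 56.5 kb downstream and 68.5 and 70.7 kb upstream of its start.

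Collagen genes differed from the rest of the list in the number and place of their peaks. At any distance 21 of the 44 were assigned a peak, and only these have known gene bounds. In the bodies of 19 of the 21 lay 61 peaks (4.09% of the list), and 15 held 2 or more. The other 23 were not examined, so peaks in them credited to a neighbour are missed and these counts are minimums. Every gene of the list with 3 or more peaks in its body was a collagen gene, 11 in all. None of the 61 midpoints lay within 1 kb of the start of the collagen gene. Of the 752 other peaks in gene bodies 453 did (60.2%), measured to the nearest start of a gene that holds them. The two-sided Fisher's exact p was 1.2e-23, over peaks, which are not independent replicates. Gene lengths were not matched, and in a short gene a body peak lies near the start by necessity. A peak deep inside another gene is missed where the list assigns that gene no peak. The p-value may in part reflect these differences. The median midpoint lay 65.8% of the way along the gene (interquartile range 39.5% to 78.5%). Of the 61 peaks, 10 had been assigned in the list to another gene. For example, 5 peaks credited to Fcnb, which encodes ficolin B, lay inside the neighbouring Col5a1.

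By collagen type, a peak was assigned at any distance to 9 of 11 fibril-forming, 7 of 9 fibril-associated, 2 of 9 network-forming, 1 of 6 type VI and 2 of 4 transmembrane genes, and to 0 of 2 multiplexins and 0 of 3 others. The difference between types was not tested. Among the assigned genes, which alone have known bounds, bodies held 36 peaks in 9 fibril-forming genes, 19 in 6 fibril-associated, 2 in 2 network-forming and 4 in 2 transmembrane genes, and none in Col6a6 of type VI. Col3a1, a fibril-forming collagen of skin and vessels, held 9 peaks between 45378525 and 45402988 on chromosome 1, in a gene of 37.4 kb. Col1a1, which encodes the main chain of type I collagen, held 3 peaks on chromosome 11 (94802714 to 94804762, 94805687 to 94807049 and 94809558 to 94811732). These 3 were among the 15 widest of the list and covered 35.7% of the 15.6 kb gene. Its partner Col1a2 held a single peak, at chromosome 6, 4483553 to 4484137, which lay 28.1 kb from the gene start. The cartilage collagens were also represented, with 5 peaks in Col2a1, 4 in Col9a1, 3 in Col9a2, 4 in Col9a3 and 3 in Col11a2. The Col9a2 peak at chromosome 4, 120724671 to 120727259, was 2589 bp wide, the second widest of the list. Peaks in collagen bodies had a median width of 641 bp, against 624 bp for all others.

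**Figure D3:**
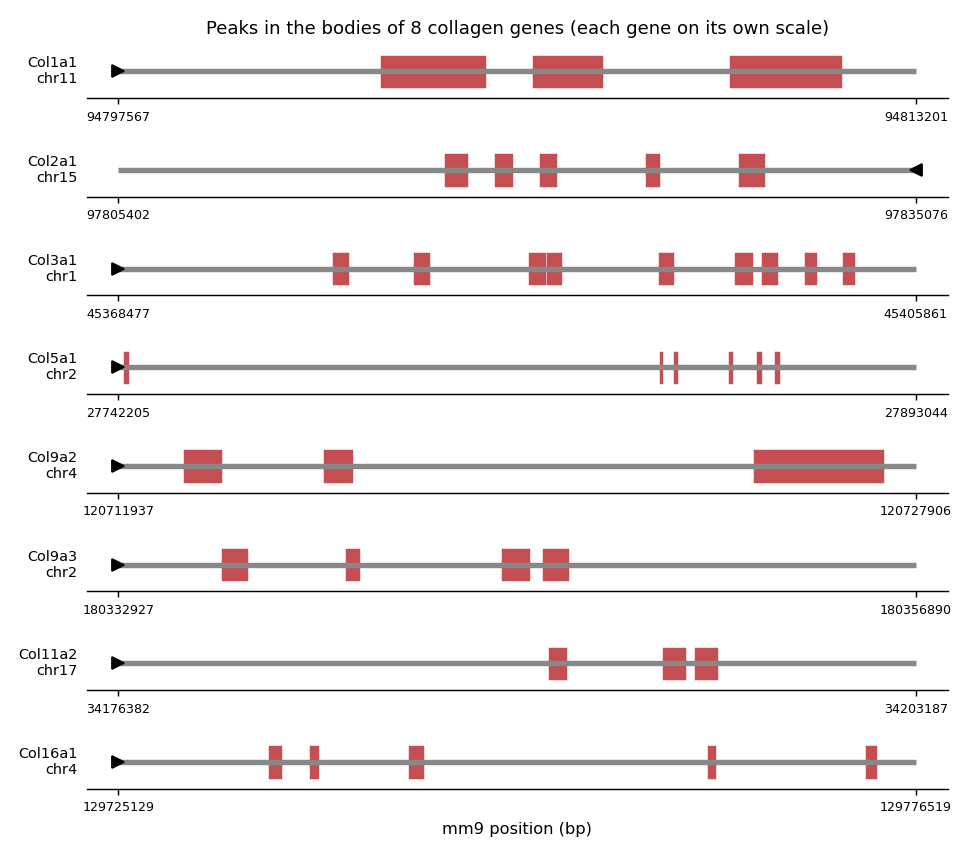
Peaks (red boxes, to scale) along the bodies of 8 collagen genes (grey lines, from gene start to gene end as given in the list; arrowheads mark the start of transcription and its direction), each on its own x axis in mm9 bp with both gene bounds printed. The boxes lie inside the genes and none reaches the start; Col3a1 carries 9 and Col1a1 3 wide ones.

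The other widest peaks were assigned to genes outside the collagen family. The widest, 17807 bp at chromosome X, 166408241 to 166426047, covered the whole of RIKEN cDNA G530011O06 gene. A second wide peak (1576 bp) lay 18.6 kb upstream of the same gene, and both were in the last Mb of the chromosome. C1ql4, a C1q-like secreted protein, had a peak of 1767 bp over its start at chromosome 15, 98917514 to 98919280. Gata2, a blood and endothelial transcription factor, had a peak of 1292 bp at chromosome 6, 88153964 to 88155255, which lay 6.28 kb inside the gene. A peak of 1387 bp assigned to Pin1, a prolyl isomerase, lay 19.8 kb from its start and within the body of Olfm2. The remaining 4 belonged to RIKEN cDNA 4632433K11 gene (1268 bp), Txn2 (1267 bp), Ccdc177 (1263 bp) and a predicted gene (1241 bp, at chromosome 11, 55203100 to 55204340).

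Peaks were unevenly spread over the chromosomes. The counts departed from chromosome length (chi-square 186.7, 19 degrees of freedom, Monte Carlo permutation p = 1e-05, the smallest that the draws can give) and from the number of protein-coding genes (chi-square 92.2, same p). The X chromosome held 25 peaks, 0.262 times the number expected from length and 0.376 times that expected from genes (exact binomial adjusted p = 6.8e-17 and 1.2e-07). The tests over chromosomes take peaks as independent, although many lay close together, so their p-values may be too small. How well reads map to each chromosome was not examined. Chromosome 15 held 81, above both expectations (59.1 and 53.5; exact binomial adjusted p = 0.0116 and 0.00248), and chromosome 6 held 56, below both (85.5 and 77.6; exact binomial adjusted p = 0.00263 and 0.0408). In all, 10 chromosomes departed from the expectation from length and 5 from that from genes. The 5 included chromosome 7 (0.722 times the expected number, exact binomial adjusted p = 0.00248) and chromosome 12 (1.41 times, exact binomial adjusted p = 0.0296). By length neither departed, with chromosome 7 at 1.16 times (exact binomial adjusted p = 0.209) and chromosome 12 at 0.968 times (exact binomial adjusted p = 0.897). Chromosomes 11 and 17 exceeded the expectation from length (113 against 69 and 84 against 50.6; exact binomial adjusted p = 5.2e-06 and 6.8e-05) but not that from gene number (110.9 and 73; exact binomial adjusted p = 0.895 and 0.287).

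Peaks were also closer together than random placement gives. Adjacent midpoints lay within 10 kb of each other in 71 cases, against 9.98 ± 3.19 (SD over 1000 random placements; permutation p = 0.001, the smallest that they can give). Of these 71 pairs 33 (46.5%) joined peaks that both lay in the bodies of collagen genes with known bounds. Without peaks in collagen bodies 38 pairs remained, still above random placement (median 9, permutation p = 0.001). The placements were uniform and kept neither the concentration of peaks at gene starts nor the uneven spacing of genes. This test therefore cannot tell clustering of peaks from clustering of gene starts.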

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

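The peaks wider than the median, the other gene list backgrounds, assignment at any distance, gene number in place of chromosome length, merging close peaks, and leaving out peaks in collagen bodies or over 5 kb wide were chosen after seeing the data. Of 60 alternative values computed, 43 kept their direction and side of the threshold or their value. Unevenness over chromosomes, clustering, the width difference and the low number of olfactory receptor targets passed their tests under each alternative run for them, and merging peaks within 1 kb left 1472. The share of peaks at gene starts follows the window by construction, at 27.2% within 500 bp, 49.8% within 5 kb and 59.1% within 10 kb. It was 38.7% among peaks wider than the median; the cause was not tested. The number of gene lists above background was 2 as reported, 0 within 1 kb, 1 within 5 kb (Hox genes), 4 within 50 kb and 4 at any distance (with the matrix and lineage lists added), and 1 among peaks wider than the median (collagens). Within 1 kb no collagen was a target (0 of 44), and the odds ratio of 0.516 there comes from the 0.5 added to each cell. With 519 peaks within 1 kb and 21896 protein-coding genes, 0 of 44 cannot show a reversed direction. The collagen odds ratio was 4.67 within 5 kb (exact test adjusted p = 0.0552), 12.4 within 50 kb and 17.7 at any distance. The wider settings can favour long genes, and gene length was not matched. The Hox odds ratio was 3.08 within 1 kb and 3.56 among peaks wider than the median, with 2 of 39 genes in each (exact test adjusted p = 0.82 and 0.619); both settings leave fewer peaks, and no other cause was tested. No paired analysis was possible because the list carries no values per library, and for the same reason no library was left out. Stricter enrichment or p-value limits, motifs and the background of the list itself were not run, as the list gives no score, holds only assigned genes and comes without sequence. Depth per library is unknown, so a gene without a peak may have been below detection, as the 0 of 44 collagens within 1 kb may in part have been.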

Other observations

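The tests in this part were chosen after the list had been seen. Beyond the groups already described, families of gene symbols with 8 or more members were tested for peaks within 10 kb of the start. Of 379 families, the collagen and Hox families passed Benjamini-Hochberg adjustment above background (exact test adjusted p = 0.00298 and 0.00622), and 0 other families did. Both hold the same target genes as the collagen and Hox lists above, so their result is not separate support for those lists. An unadjusted exact test p under 0.05 was reached by 14 families above background, collagens and Hox included. Some of 379 families would reach it by chance, so this count is no sign of further enriched families. Next after the collagen and Hox families was Pax, developmental transcription factors, with 3 of 9 genes (Pax3, Pax7 and Pax9, exact test adjusted p = 0.257). Vomeronasal receptors fell below background with 0 of 355 (exact test adjusted p = 0.00078).

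Small RNA genes were the assigned gene of 62 peaks (4.16%), of which 17 were U6 and 15 microRNA genes. Within 1 kb of the start lay 7 of the 62, and none of those 7 was a U6 gene. Of the 7, a peak of 596 bp covered a gene annotated as Vertebrate telomerase RNA at chromosome 3, 30494102 to 30494697, and another overlapped a second such gene at chromosome 3, 96218157 to 96218739. A peak lay 0.496 kb upstream of a 7SK RNA gene on chromosome 9. Others overlapped microRNA genes at chromosome 8, 130882894 to 130883172, and chromosome X, 50405619 to 50406506. How many small RNA genes chance would give was not computed, since no mm9 annotation was used.

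The pattern most worth a second look is the run of peaks inside collagen genes. Gene length is argued against as the whole cause: 78.9% of the collagen genes with a body peak held 2 or more (15 of 19), against 5.64% of other genes with a body peak and a length within 1.5 times (permutation p = 1e-05, the smallest that the draws can give). Strong transcription in fibroblasts stays open, since expression was not measured here. Body peaks were seen in 4.44% of other matrix genes (2 of 45) and 43.2% of collagens (19 of 44; two-sided Fisher's exact p = 1.2e-05), but bounds were known for only 7 and 21 of them, and the rest count as without a peak. A peak was assigned at any distance, which needs no gene bounds, to 15.6% of the matrix genes (7 of 45) and 47.7% of the collagens (21 of 44, two-sided Fisher's exact p = 0.00136). Peaks without a symbol are not counted there. Long genes and genes far from others can collect more peaks at any distance, and gene length was not matched. A candidate explanation is sequence coding for the Gly-X-Y repeats of the collagen triple helix: of 36 genes outside the collagen family with a collagen-like domain, not noticed beforehand, 6 were seen with a body peak (16.7%), against 3.04% of the other protein-coding genes (two-sided Fisher's exact p = 0.00072).

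Bounds are missing here too for genes without an assigned peak. By assignment at any distance the shares were 16.7% (6 of 36) and 4.87% (two-sided Fisher's exact p = 0.00744), and among genes with known bounds 6 of 6 and 62.5% held a body peak (two-sided Fisher's exact p = 0.0898). Counting only peaks more than 1 kb from the start of the gene that holds them, 3 of the 36 genes (8.33%) and 1.24% of the others had one (two-sided Fisher's exact p = 0.0103), a result that rests on Marco, Otol1 and Sftpd. With the 4 such genes that had been noticed first, 10 of 40 held a body peak at any position (25%). The 10 comprise C1ql1, C1ql2, C1ql3 and C1ql4, secreted C1q-like proteins, C1qc of the complement system, the collectins Colec12 and Sftpd, ficolin Fcnb, the macrophage receptor Marco and the inner ear protein Otol1. Colec12 and Fcnb were among the 4 noticed first, and the others of the 4 were C1q or C1q-like genes. Besides Marco, Otol1 and Sftpd, the 6 were also C1q or C1q-like genes, with peaks within 1 kb of the start. Those are related to genes noticed first and are not independent of them. The peaks lay, for example, at chromosome 1, 122237584 to 122238428 in C1ql2, chromosome 14, 41989604 to 41990128 in Sftpd and chromosome 3, 69830274 to 69830776 in Otol1. Whether these peaks cover the exons that encode the repeats was not examined without mm9 exons, and reads shared between similar repeat sequences were not tested either; both stay open, and no explanation tied to the genotype was tested, since the list has no values per library.

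On the X chromosome 3 of the 25 peaks lay in its last Mb, between 166394171 and 166436284. Among them was the peak of 17807 bp, against 2589 bp for the next widest of the list. The cause of this width was not tested. Around Prdm5 on chromosome 6, 3 peaks lay within 10 Mb of the gene start, its own included, where the density of the chromosome gives 7.5.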
